A study of Mus musculus with 16 samples.

How the data were processed

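Whole skin from 16 mice was compared, 4 each of control, EKO, MKO and EMdKO, with group and mouse number read from the labels. Libraries were made from total RNA of snap-frozen skin with the Ion AmpliSeq Transcriptome Mouse kit, per the labels' protocols. The deposited files hold a raw read count for each targeted transcript, made with HTSeq 0.6.0, per the submitters' processing notes. Those notes also name DESeq2 1.18.1, but no DESeq2 output was used here. The aligner, the genome build and the annotation were not given in the sources used here.

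Each file lists 23930 targets by RefSeq accession, followed by 5 HTSeq summary lines that were kept out of library sizes and tests and held between 3.111 and 5.252% of the reads. Symbols were assigned to 22562 targets, 22452 through a RefSeq table of GRCm38.p6 and 110 through GENCODE vM21, and the 1368 targets without a symbol held at most 0.31% of the counts of a library. Library depth was 6962474 to 12086327 counts, and the 10 largest targets held 8.36 to 13.92% of them. No pair of libraries looked like copies of each other, as the smallest chi-square per degree of freedom between any pair was 15.25. The 4 Y-linked genes were found in all 16 libraries and Xist had at most 5 counts in any, so no term for sex was fitted.

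Counts were modelled in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood, TMM scaling, the default expression filter, 1 mean per group). The fit held 13633 genes and 12 residual degrees of freedom, and its biological coefficient of variation was 0.31 (common dispersion 0.0964, prior degrees of freedom 4.14). The 7 contrasts fixed before the data were examined were each knockout against control, the knockouts against each other and the interaction, and adjusted p under 0.05 (BH) was called a change. The mean effect of each Cre was added after the data were seen. Log2 CPM used a prior count of 2, and CPM is a count scaled to a common library total. Intervals from counts cover counting error only, and a count of 0 leaves room for up to 3 counts at the 95% level.

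Gene lists were written before the files were opened: 31 lists of epidermal, immune, follicle, gland, matrix and other tissue genes, of which 30 had at least 3 tested members. The red blood cell list had 2 and was not tested. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, BH adjusted over the 30 lists, and again with the correlation estimated from the data. Named genes were chosen by rule. Zc3h12a, Krt14 and Lyz2 were always reported. Where fewer than 5 genes were called, the called genes and those next in p were taken, up to 5 together. Otherwise the 8 largest changes in each direction were taken among called genes with an official symbol and a mean log2 CPM of at least 1 that did not overlap between groups (overlap was not considered for the mean effects). For each called list the 4 members with the smallest p were taken. Values of 4 against 4 mice outside the fits were tested by exact permutation over 70 assignments, as were the 30 list scores in the 6 contrasts between groups.

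The alternatives were DESeq2 1.42.0, limma-voom with sample quality weights, other scaling, no filter or a stricter filter (CPM of 1 in 4 libraries), fits on the compared groups alone, the mouse number as a block (from the titles, and from the file names as an addition after the data were seen), muscle and hair covariates, fry, and each library left out. The hair covariate for list tests was added after the data were seen. The pipeline was tested on simulated data of the same size, with 50 genes changed at each fold. Genes were simulated independently, and the changed ones had a mean log2 CPM of at least 1 and the same shift in all 4 EKO mice. No mouse deviated from its group and no tissue differed between mice, so the recovery below does not give the power of the real contrasts. edgeR recovered 52, 96, 98 and 100% of genes changed by 1, 2, 3 and 5 on the log2 scale, with 10 false calls among 183. DESeq2 made 34 false calls among 218 and limma-voom 11 among 179. Tables and figures used python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.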

Results

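RNA was measured in the whole skin of 12-week-old mice that lacked MCPIP1 in keratinocytes, in myeloid cells, in both cell types or in neither. MCPIP1, also called Regnase-1, is an endoribonuclease encoded by Zc3h12a that degrades the mRNAs of inflammatory mediators. EKO mice carried floxed Zc3h12a with Cre driven by Krt14, which is active in basal keratinocytes. MKO mice carried the same floxed gene with LysM-Cre, a Cre inserted in the Lyz2 gene of macrophages and neutrophils, and EMdKO mice carried both Cre genes. Control mice had the floxed gene without Cre. Each group held 4 mice, named in the labels as separate animals, which gave 16 libraries. The libraries were made with a targeted kit that amplifies a short stretch of each transcript, so each value is a count of reads per amplicon target. Between 6962474 and 12086327 counts fell on the 23930 targets of a library, and 13633 targets had enough counts to be tested. The Y-linked gene Ddx3y lay between 73.3 and 102 CPM, counts scaled to a common library total, in the 16 libraries. Below, group levels are mean CPM ± SD of 4 mice, and log2 fold changes carry an approximate standard error. It was derived from the test, as the absolute change divided by the square root of its F statistic. BH marks Benjamini-Hochberg adjustment.

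Zc3h12a, the targeted gene, was lower in both groups with Krt14-Cre. It stood at 19.4, 21.7, 30.3 and 27.4 CPM in control mice 1 to 4 and at 17.1, 35, 29.2 and 24.8 CPM in the MKO mice. The EKO mice had 11.7, 7.07, 7.40 and 8.41 CPM, and the EMdKO mice had 5.47, 5.69, 5.71 and 4.41 CPM. Each EKO and EMdKO value lay below every control and MKO value, and an exact permutation test against the controls gave p = 0.0286 for EKO and for EMdKO, the smallest that 4 against 4 mice can give. MKO did not differ from control in that test (exact permutation p = 0.771). EMdKO also lay below EKO in every mouse (exact permutation p = 0.0286). In the fit over all genes, Zc3h12a fell by 2.21 ± 0.24 on the log2 scale in EMdKO (edgeR quasi-likelihood, BH adjusted p = 0.000448), while the EKO change of -1.52 ± 0.23 did not pass (edgeR quasi-likelihood, BH adjusted p = 0.082). The gene lies on chromosome 4 from 125118423 to 125127840 on the minus strand in the GENCODE annotation of GRCm38, a build the count files do not name. The labels give neither the floxed exons nor the amplicon position, so whether the counted stretch is the deleted one is unknown, and whole skin holds cells without Cre.

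Lyz2, the host gene of LysM-Cre, had lower levels in both groups that carry that Cre. It measured 218 ± 36.3 CPM in MKO and 230.4 ± 51.4 in EMdKO, against 394 ± 103 in control and 370.2 ± 163 in EKO. Neither contrast against control passed the test over all genes (log2 fold changes -0.86 ± 0.30 and -0.78 ± 0.30; edgeR quasi-likelihood, BH adjusted p = 0.355 and 0.5). Krt14, the basal keratinocyte keratin whose promoter drives the other Cre, stood at 1131 ± 104 CPM in control, 2382 ± 1409 in EKO, 955 ± 338 in MKO and 1596 ± 396 in EMdKO, and in the fit of all libraries no contrast between groups changed it past the threshold. Without EKO mouse 1, Krt14 rose in EKO against control by 1.38 ± 0.29 (edgeR quasi-likelihood, BH adjusted p = 0.0319) and was also called against MKO, as it was with DESeq2 and limma-voom. Lyz2 was called in EKO against MKO and for myeloid loss without EKO mouse 1 and with limma-voom, and for myeloid loss with DESeq2.

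**Figure D1:**
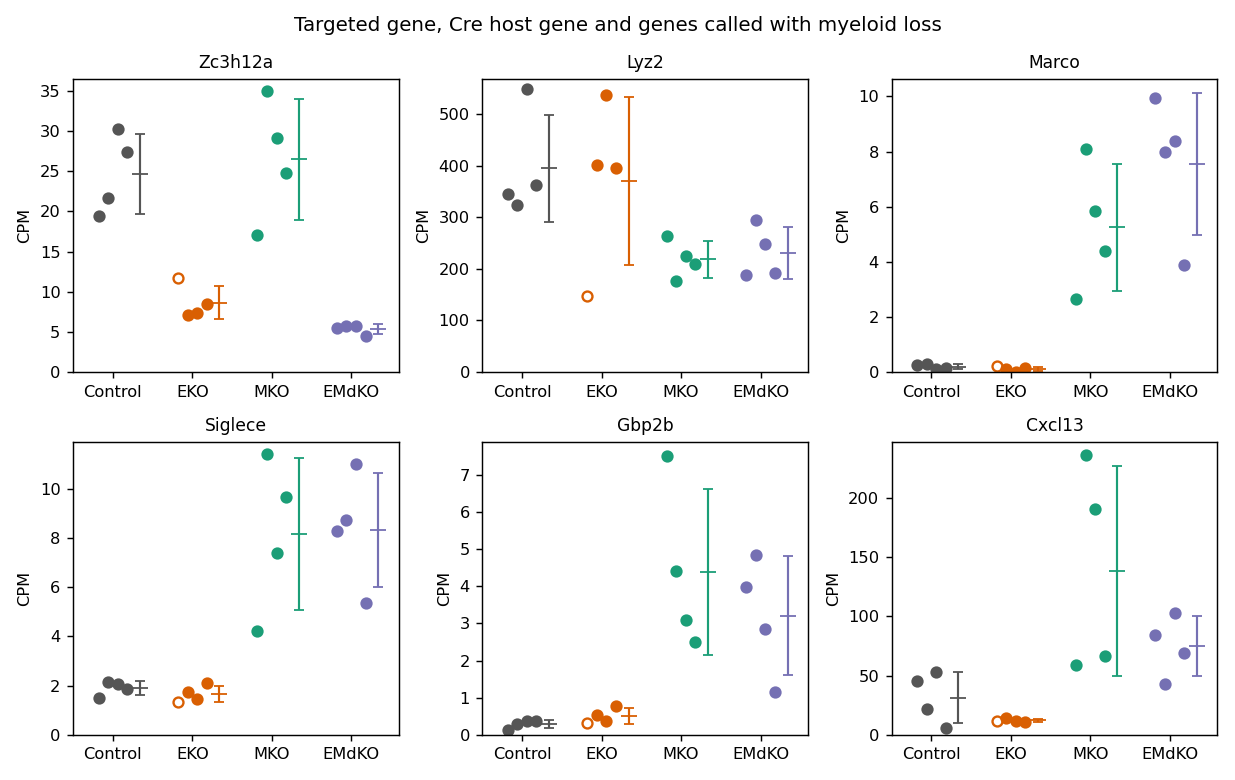
Levels in CPM (linear vertical axes) of Zc3h12a, Lyz2, Marco, Siglece, Gbp2b and Cxcl13 in the 4 groups; each point is 1 mouse, the bar beside the points is the mean ± SD of 4 mice, and the open circle is EKO mouse 1. Zc3h12a lies between 4.41 and 11.7 CPM in the mice with Krt14-Cre and between 17.1 and 35 CPM in the others, and Marco averages 5.25 and 7.55 CPM in MKO and EMdKO against 0.188 CPM in control.

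Loss in keratinocytes alone was read from EKO against control. Zc3h12a had the smallest p and interleukin-36 genes of stressed epidermis and a protease inhibitor gene followed, though none passed. Il1f6, which encodes IL-36 alpha, averaged 62.9 ± 42.1 CPM in EKO and 1.68 ± 0.0798 in control (log2 fold change 5.21 ± 0.87), and Il1f8, which encodes IL-36 beta, averaged 47.1 ± 28.2 and 6.57 ± 0.722 CPM (2.84 ± 0.52). Serpinb3a, a serine protease inhibitor, averaged 27 ± 25.3 against 0.137 ± 0.115 CPM. None of the 13633 genes passed in edgeR's quasi-likelihood test with BH adjustment, where Zc3h12a reached an adjusted p of 0.082, Il1f6 and Serpinb3a one of 0.121 and Il1f8 one of 0.154. At an unadjusted p under 0.05 the test counted 940 genes, with 682 expected by chance, and DESeq2 called 59 genes, limma-voom 4, a fit with no filter on low counts 3 and a fit with a skeletal muscle covariate 7. The count was 127 without EKO mouse 1 and 1 without MKO mouse 1.

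For Il1f6 the spread within EKO came from EKO mouse 1. Its Il1f6 level was 0.516 CPM, whereas the other EKO mice lay between 79.3 and 92.4 CPM. With that library left out, as each library was in turn, 127 genes changed, 113 higher and 14 lower. Il1f6 then rose by 5.62 ± 0.29 on the log2 scale (edgeR quasi-likelihood, BH adjusted p = 4.51e-08), Serpinb3a by 7.80 ± 0.77 (0.00024), the cornified envelope gene Lce1g by 3.81 ± 0.58 (0.00313), and the suprabasal keratin Krt1 by 2.50 ± 0.35 (0.0016), all in the same test. Hornerin (Hrnr), a barrier protein, rose by 2.13 ± 0.23 (0.000299) and the antimicrobial peptide gene Defb14 by 3.15 ± 0.50 (0.00475). The controls held at most 3 Serpinb3a counts, so the size of that fold change is rough. Zc3h12a fell by 1.70 ± 0.24 in that fit (edgeR quasi-likelihood, BH adjusted p = 0.0018). EKO mouse 1 stood out by its levels of such epidermal genes, Il1f6 among them. The p-values without it therefore describe the other EKO mice and are no independent support for a change in EKO.

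Gene lists fixed in advance pointed to the same layers of the skin when tested over genes. Tested over mice by exact permutation, 0 of 180 comparisons of a list score between groups passed (BH). The smallest p that test can give is 0.0286. With adjustment over 30 lists, a list at that p passes only if many others reach it too. Cell cycle in EMdKO against EKO, for example, had that exact permutation p and a BH adjusted p of 0.286. The 0 is therefore no evidence that list scores did not differ. In EKO against control the lowest exact permutation p was 0.114, for the IL-1, IL-36, IL-17 and IL-6 family list. Of 20 cornified envelope genes, 19 had positive log2 fold changes in EKO with a median of 0.56 (camera adjusted p = 1.02e-08, but adjusted p = 0.684 with an estimated correlation). Adjusted over the list alone, 5 of the 20 passed, against 0 over all genes. Hrnr was 509.6 ± 279.9 against 148 ± 36.6 CPM and Krt1 was 3489 ± 2075 against 798 ± 400.3. The IL-1, IL-36, IL-17 and IL-6 family list had 9 of 11 positive members (camera adjusted p = 1.41e-05, adjusted p = 0.684 with an estimated correlation), and 6 passed when adjusted over the list alone, against 0 over all genes. Il1f9 (IL-36 gamma) and Il1a were among its leading members, at 234 ± 121 and 26.5 ± 16 CPM against 66.5 ± 19 and 6.56 ± 0.718. Antimicrobial peptides and alarmins had 9 of 12 positive members (camera adjusted p = 0.00283, adjusted p = 0.782 with an estimated correlation), 4 of them past the threshold adjusted over the list alone. Their leading members were Defb14 at 14 ± 9.44 against 2.11 ± 1.57 CPM and the neutrophil and keratinocyte alarmin S100a9 at 106 ± 144 against 7.92 ± 11.2. EKO mouse 3 held 316 CPM of S100a9, and without it the score difference of the list fell to 0.55 and its call was lost (camera adjusted p = 0.0881). Without EKO mouse 1, the counts over all genes were 4 cornified envelope, 6 cytokine and 3 antimicrobial genes higher, and adjusted over the list alone 9, 7 and 5.

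All 19 cell cycle genes had positive log2 fold changes in EKO (median 0.50; camera adjusted p = 1.6e-09, adjusted p = 0.684 with an estimated correlation), led by Cdc20, an activator of the anaphase-promoting complex, at 20.1 ± 4.31 against 11.1 ± 5.44 CPM. No cell cycle gene passed over all genes or adjusted over the list alone. Sebaceous gland markers had 12 of 15 positive members (camera adjusted p = 0.00283, adjusted p = 0.782 with an estimated correlation), among them the wax ester synthase gene Awat1 at 32.9 ± 22 against 8.77 ± 4.9 CPM. Collagen and matrix genes (19 of 21 negative, camera adjusted p = 0.0129), adipocyte markers (12 of 15 negative, 0.0272) and melanocyte markers (8 of 8 negative, 0.0497) leaned lower. With an estimated correlation the adjusted p of each of these 3 lists was 0.869. Their leading members were the matrix cross-linking enzyme gene Loxl1 (-0.53 ± 0.22), lipoprotein lipase Lpl (-0.63 ± 0.37) and the melanocyte transcription factor gene Mitf (-0.61 ± 0.22), none past the threshold. Of the 8 lists called in EKO, 3 (cornified envelope, cytokines and cell cycle) kept their calls in all 16 fits that left out a library, and the others did not. The sebaceous and melanocyte lists had an adjusted p of 0.194 and 0.735 without control mouse 1, the matrix list 0.458 without control mouse 3 and the adipocyte list 0.374 without control mouse 4. The melanocyte score difference turned from -0.63 to 0.07 without control mouse 1, so that lean rested on this mouse.

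**Figure D2:**
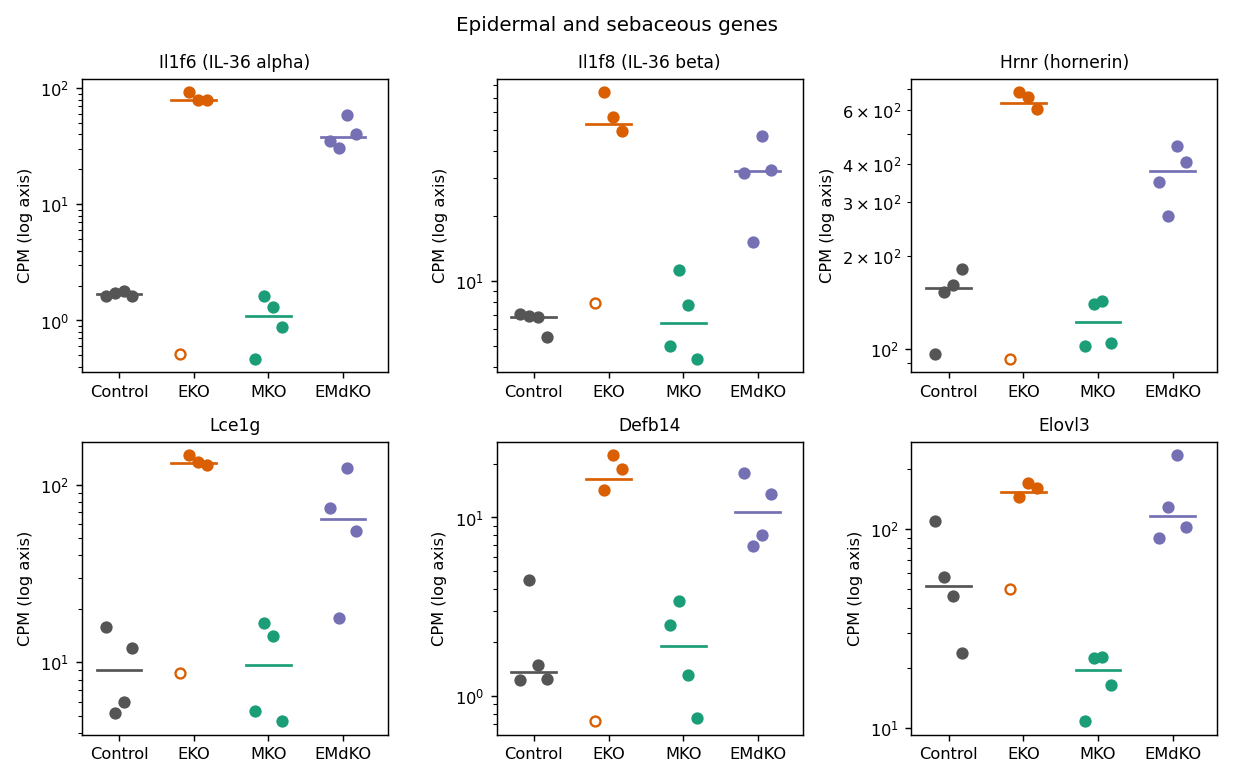
Levels in CPM (logarithmic vertical axes) of Il1f6, Il1f8, Hrnr, Lce1g, Defb14 and Elovl3 in the 4 groups; each point is 1 mouse, the line is the group median and the open circle is EKO mouse 1. Il1f6 lies between 79.3 and 92.4 CPM in EKO mice 2 to 4 and between 30.4 and 58.5 CPM in EMdKO, but at 0.516 CPM in EKO mouse 1 and at most 1.78 CPM in control and MKO.

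Loss in myeloid cells alone was read from MKO against control. Of 13633 genes, 4 rose and 0 fell, and each of the 4 was higher in every MKO mouse than in any control. An unadjusted p under 0.05 was reached by 1306 genes. Marco, a scavenger receptor of macrophages, rose from 0.188 ± 0.0938 to 5.25 ± 2.3 CPM (log2 fold change 4.77 ± 0.52; edgeR quasi-likelihood, BH adjusted p = 0.00123). Each control library held only 1 or 2 Marco counts, so the size of this fold change is rough. Siglece, an inhibitory sialic acid receptor of myeloid cells, rose from 1.89 ± 0.296 to 8.16 ± 3.09 CPM (2.10 ± 0.31; edgeR quasi-likelihood, BH adjusted p = 0.0137). The interferon-inducible GTPase gene Gbp2b rose by 3.83 ± 0.54 on the log2 scale and the Mas-related receptor gene Mrgprg by 5.14 ± 0.73 (edgeR quasi-likelihood, BH adjusted p = 0.0126 for both). The controls held at most 4 Gbp2b and 7 Mrgprg counts, so these fold changes are rough as well. Marco lies on chromosome 1 (120474538 to 120505024), Siglece on chromosome 7 (43651070 to 43660161) and Gbp2b on chromosome 3 (142594847 to 142619179) in the GENCODE annotation of GRCm38. By comparison, 3.08% of all tested genes did not overlap between these groups, and 2 of the 70 assignments of 8 mice give no overlap by chance. The count fell to 1 without any 1 of the 4 control mice, to 1 with the hair shaft score as a covariate and to 0 with limma-voom, whereas DESeq2 called 116 genes, 88 of them lower. Marco alone was called in all 16 fits that left out a library.

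Hair follicle and pigment genes were lower in MKO as groups. All 27 hair shaft and inner root sheath genes had negative log2 fold changes (median -6.90; camera adjusted p = 5.45e-17, adjusted p = 0.372 with an estimated correlation), and 26 passed when adjusted over the list alone, against 0 over all genes. The hair shaft keratin Krt35 averaged 0.249 ± 0.423 CPM against 35.7 ± 52.5 in control, and the follicle transcription factor gene Foxn1 9.84 ± 2.72 against 52.6 ± 65.3. The hair score, the mean log2 CPM of the list, ran from -0.94 to 9.56 among the controls and from -1.14 to 3.01 in MKO, and did not pass over mice (exact permutation p = 0.114, BH adjusted p = 0.429). Without control mouse 1, which held 113 CPM of Krt35 and 150 of Foxn1, the difference fell from -5.03 to -3.53. Melanocyte markers moved with it (7 of 8 negative, camera adjusted p = 0.00073, adjusted p = 0.475 with an estimated correlation; 6 lower adjusted over the list alone), as in the pigment enzyme gene Tyrp1 at 3.64 ± 3.55 against 75.4 ± 103 CPM. The same control mouse held 227 CPM of Tyrp1 (other controls 1 to 49.9), and without it the melanocyte difference fell from -1.80 to -1.10. Cell cycle genes were negative in 19 of 19 (median -0.66; camera adjusted p = 1.16e-09, adjusted p = 0.372 with an estimated correlation), with 2 lower adjusted over the list alone. Control mouse 1 stood apart with a cell cycle score of 4.56 (other controls 3.33 to 3.47), and without it the difference from control fell from -0.64 to -0.35 (camera adjusted p = 2.24e-05). Stress keratins and wound-activated genes were negative in 12 of 12 (camera adjusted p = 1.59e-05, adjusted p = 0.372 with an estimated correlation; 5 lower adjusted over the list alone), including Krt16 at 16.5 ± 8.12 against 129.6 ± 161 CPM and Krt17 at 695 ± 296 against 1459 ± 405. Control mouse 2 held 370 CPM of Krt16 (other controls 29.9 to 80.1), and without it the stress keratin difference fell from -1.16 to -0.73. Antimicrobial genes were negative in 12 of 12 (camera adjusted p = 0.00556, adjusted p = 0.475 with an estimated correlation), led by S100a7a at 1.85 ± 0.765 against 37.1 ± 56.2 CPM, of which control mouse 1 held 121. That call was lost without control mouse 2 (camera adjusted p = 0.0702).

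Antigen presentation genes and B and plasma cell genes leaned higher in MKO, while the scores of T and NK cells, dendritic cells, neutrophils and mast cells differed from control by 0.10, 0.02, -0.07 and 0.10. Antigen presentation and interferon-gamma genes were positive in 21 of 23 (median 0.41; camera adjusted p = 7.88e-06, adjusted p = 0.475 with an estimated correlation), with the class II gene H2-Eb1 at 364 ± 36.9 against 237 ± 92.2 CPM and the GTPase gene Gbp4 at 88.4 ± 49.6 against 32.3 ± 25.4. Control mouse 1 had the lowest score of this list, 5.54 where the other controls had 6.32 to 6.75 and MKO 6.49 to 6.99, and without it the difference fell from 0.47 to 0.22 (camera adjusted p = 0.0141). None of the 23 passed over all genes or adjusted over the list alone. All 4 tested B and plasma cell genes were positive (camera adjusted p = 6.64e-05, adjusted p = 0.136 with an estimated correlation), and 2 passed adjusted over the list alone. These were Jchain, the joining chain of secreted antibodies, at 12.8 ± 13.2 against 0.405 ± 0.312 CPM, and Cd79b, part of the B cell receptor, at 5.07 ± 1.85 against 1.99 ± 0.447. Skeletal muscle markers were positive in 20 of 20 (median 0.53; camera adjusted p = 0.00678, adjusted p = 0.908 with an estimated correlation), but this lay mainly in MKO mouse 1, with a score of 11.84 where the other MKO mice had 10.23 to 10.56, and control mouse 1, with 9.71 where the other controls had 10.49 to 10.53 (exact permutation p = 0.486), and without MKO mouse 1 the camera adjusted p was 0.781. In the 16 fits that left out a library, 6 of the 11 lists called in MKO kept their calls throughout (hair shaft, melanocytes, cell cycle, stress keratins, antigen presentation, B and plasma cells).

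Loss in both cell types was read from EMdKO against control. Of 13633 genes, 3 rose and 1 fell. Marco rose to 7.55 ± 2.58 CPM (log2 fold change 5.29 ± 0.52; edgeR quasi-likelihood, BH adjusted p = 0.000253), Siglece to 8.35 ± 2.33 CPM (2.13 ± 0.31; edgeR quasi-likelihood, BH adjusted p = 0.0145) and Gbp2b to 3.21 ± 1.59 CPM (3.38 ± 0.54; edgeR quasi-likelihood, BH adjusted p = 0.0351). Zc3h12a was the gene that fell, and all 4 genes separated every EMdKO mouse from every control, as 3.67% of all tested genes did. The fold changes of Marco and Gbp2b rest on the same low control counts as in MKO and are rough. An unadjusted p under 0.05 was reached by 1112 genes. The epidermal cytokine genes stood between the EKO and control levels without passing over all genes: Il1f6 averaged 41.1 ± 12.3 CPM and Il1f8 31.6 ± 13 (edgeR quasi-likelihood, BH adjusted p = 0.14 and 0.236). Without EKO mouse 1, which is in neither group, 40 genes were called, 36 higher and 4 lower. That mouse enters this contrast through the shared spread, the filter on low counts and the scaling, which were not separated. The count was 2 without EMdKO mouse 1 or 2 or without control mouse 2, 3 or 4, and the Gbp2b call was lost in 11 and the Siglece call in 7 of the 16 fits that left out a library. Siglece also lost its call with the mouse numbers of the file names as a block (adjusted p = 0.186). Gbp2b lost its call with the mouse numbers of the titles as a block, with limma-voom, with the hair covariate and in the fit on the 2 groups alone. DESeq2 called 73 genes, limma-voom 8 and a fit on the 2 groups alone 10.

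Epidermal, sebaceous and cytokine lists were higher in EMdKO than in control. The cytokine list was positive in 9 of 11 (camera adjusted p = 1.16e-05, adjusted p = 0.368 with an estimated correlation; 4 higher adjusted over the list alone, 0 over all genes). Cornified envelope genes were positive in 18 of 20 (camera adjusted p = 0.000128, adjusted p = 0.549 with an estimated correlation), with Lce1g at 67.5 ± 44 against 9.78 ± 5.1 CPM. Sebaceous gland genes were positive in 13 of 15 (median 0.78; camera adjusted p = 1.16e-05, adjusted p = 0.368 with an estimated correlation), including Fa2h, a fatty acid hydroxylase gene, at 682 ± 479 against 225 ± 95.7 CPM. Antimicrobial genes were positive in 9 of 12 (camera adjusted p = 0.0181) and basal keratinocyte genes in 11 of 15 (0.034), with an adjusted p of 0.549 and 0.679 with an estimated correlation. The antimicrobial call was lost without control mouse 4 (0.157) and the basal call without control mouse 1 (0.508). Genes of NF-kB feedback were positive in 13 of 18 (camera adjusted p = 0.00138, adjusted p = 0.368 with an estimated correlation), and 4 passed adjusted over the list alone. Among them Zc3h12c, a paralog of the targeted gene, was 83.5 ± 18.6 against 42.2 ± 5.43 CPM and Nfkbiz, an inducible NF-kB cofactor gene, was 501 ± 118 against 288 ± 118. The list of mRNAs described as MCPIP1 targets was positive in 8 of 11 (camera adjusted p = 0.00212, adjusted p = 0.368 with an estimated correlation; 3 higher adjusted over the list alone), with the NF-kB subunit gene Rel at 125 ± 26.1 against 65.2 ± 19.6 CPM and the T cell costimulator gene Icos at 2.1 ± 0.228 against 0.852 ± 0.27. The NF-kB call was lost without control mouse 1 (0.107) and the target call without control mouse 4 (0.0897).

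Antigen presentation genes were positive in 22 of 23 in EMdKO (camera adjusted p = 1.06e-07, adjusted p = 0.368 with an estimated correlation), with B2m, the light chain of class I molecules, at 2441 ± 724 against 1520.0 ± 300.3 CPM. Without control mouse 1 the difference of this list score fell from 0.48 to 0.24 (camera adjusted p = 0.00886). B and plasma cell genes were positive in 4 of 4 (camera adjusted p = 0.0011) and immediate early and heat shock genes in 11 of 14 (0.0496), with an adjusted p of 0.368 and 0.549 with an estimated correlation. The immediate early score was 7.05 in EMdKO mouse 3 and 6.16 to 6.23 in the others, and without mouse 3 the camera adjusted p of the list was 0.513. Hair shaft genes were negative in 27 of 27 (median -3.17; camera adjusted p = 1.74e-10), melanocyte markers in 8 of 8 (0.00138) and collagen and matrix genes in 18 of 21 (1.71e-05). With an estimated correlation the adjusted p was 0.531 for the first 2 of these and 0.368 for the matrix list. The microfibril gene Mfap5 averaged 27.9 ± 7.72 CPM in EMdKO and 58 ± 10.4 in control, and the collagen gene Col5a2 103 ± 27.4 and 170.3 ± 52.5. The hair score of EMdKO mouse 3 was 6.76, and those of the other EMdKO mice lay between -1 and 0.66. Without control mouse 1 the hair difference fell from -3.64 to -2.14 and the melanocyte difference from -1.40 to -0.70, where the melanocyte call was lost (camera adjusted p = 0.107). Of the 13 lists called in EMdKO against control, 7 kept their calls in all 16 fits that left out a library (cornified envelope, cytokines, antigen presentation, collagen and matrix, B and plasma cells, hair shaft, sebaceous gland).

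**Figure D3:**
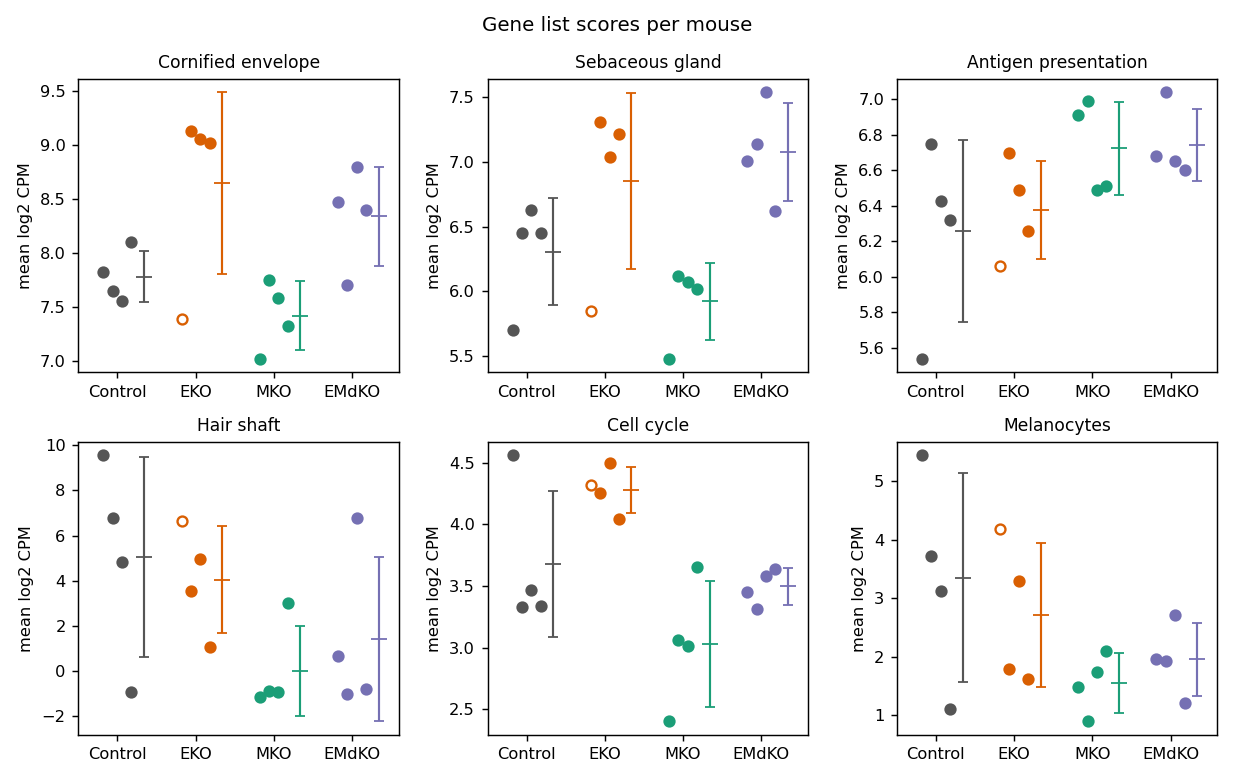
Scores of the cornified envelope, sebaceous gland, antigen presentation, hair shaft, cell cycle and melanocyte lists (mean log2 CPM of the list's members, vertical axes) in the 4 groups; each point is 1 mouse, the bar is the mean ± SD of 4 mice and the open circle is EKO mouse 1. The cornified envelope score is 7.39 in EKO mouse 1 and between 9.02 and 9.13 in the other EKO mice, and the hair shaft score runs from -0.94 to 9.56 among the controls.

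What myeloid loss added to keratinocyte loss was read from EMdKO against EKO. Marco was 7.55 ± 2.58 CPM in EMdKO and 0.106 ± 0.0863 in EKO (log2 fold change 5.96 ± 0.55; edgeR quasi-likelihood, BH adjusted p = 9.85e-05), and Siglece was 8.35 ± 2.33 and 1.66 ± 0.339 (2.33 ± 0.31; edgeR quasi-likelihood, BH adjusted p = 0.00806). These were the 2 calls, both higher in every EMdKO mouse than in any EKO mouse, and 5.57% of all tested genes did not overlap between these groups. The EKO mice held at most 2 Marco counts, so the size of its fold change is rough. An unadjusted p under 0.05 was reached by 899 genes. Without EKO mouse 1, 2 or 3 the count was 1, the Siglece call being lost, and DESeq2 called 9 genes. Cell cycle genes were negative in 19 of 19 (median -0.75; camera adjusted p = 2.31e-15, adjusted p = 0.343 with an estimated correlation), and 10 were lower adjusted over the list alone, against 0 over all genes. The replication helicase gene Mcm6 averaged 37.1 ± 4.76 CPM against 59.6 ± 4.42 in EKO. Immediate early and heat shock genes were positive in 13 of 14 (camera adjusted p = 0.000325, adjusted p = 0.343 with an estimated correlation), led by the phosphatase gene Dusp1 at 136 ± 66.8 against 58.4 ± 12.9 CPM. EMdKO mouse 3 stood apart with 234 CPM of Dusp1 (other EMdKO mice 89.4 to 119) and a list score of 7.05 (6.16 to 6.23), and without it the score difference fell from 0.65 to 0.44. Hair shaft genes were negative in 17 of 27 (camera adjusted p = 2.27e-05, adjusted p = 0.852 with an estimated correlation). Antigen presentation genes were positive in 18 of 23 (camera adjusted p = 0.000373), MCPIP1 target mRNAs in 10 of 11 (0.00948), B and plasma cell genes in 3 of 4 (0.00948), NF-kB feedback genes in 12 of 18 (0.0306), adipocyte markers in 14 of 15 (0.0255) and T and NK cell genes in 12 of 17 (0.0488). With an estimated correlation, every list in this contrast had an adjusted p of 0.343 or more. Only 3 of the 11 lists called here (cell cycle, immediate early and hair shaft) kept their calls in all 16 fits that left out a library, and without EKO mouse 1 the adjusted p was 0.38 for MCPIP1 targets, 0.26 for NF-kB genes, 0.0728 for antigen presentation, 0.0927 for B and plasma cells and 0.915 for T and NK cells. Adipocytes had 0.268 without EKO mouse 2. The score difference of T and NK cells turned from 0.25 to -0.04 without EKO mouse 1. The class II gene H2-Aa was 1098 ± 266 CPM in EMdKO against 602 ± 68.2 in EKO, and the T cell adhesion gene Cd2 was 10.8 ± 2.23 against 6.09 ± 1.7.

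What keratinocyte loss added to myeloid loss was read from EMdKO against MKO. Zc3h12a fell by 2.32 ± 0.24 on the log2 scale (edgeR quasi-likelihood, BH adjusted p = 0.000497) and was the only call. The fatty acid elongase gene Elovl3, a sebaceous gland marker, was 139 ± 65.3 CPM in EMdKO against 18.2 ± 5.71 in MKO (log2 fold change 2.93 ± 0.47; edgeR quasi-likelihood, BH adjusted p = 0.0812), and Il1f6 was 41.1 ± 12.3 against 1.08 ± 0.511 (5.21 ± 0.91; edgeR quasi-likelihood, BH adjusted p = 0.0814). Tox3 and Aox4 ranked beside them, at -2.86 ± 0.48 and 3.31 ± 0.58 on the log2 scale. An unadjusted p under 0.05 was reached by 1012 genes, and 5.99% of tested genes did not overlap. Without EKO mouse 1, 95 genes were called, without control mouse 4 the count was 3 and without control mouse 1 it was 2. These mice are in neither group and enter through the shared spread, the filter on low counts and the scaling. DESeq2 called 147 genes (113 higher), limma-voom 8, a fit on the 2 groups alone 90, a fit with no filter on low counts 9 and fits with a muscle or hair covariate 10 and 2.

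Sebaceous gland genes were positive in 14 of 15 between EMdKO and MKO (median 1.17; camera adjusted p = 2.07e-09, adjusted p = 0.198 with an estimated correlation), and 7 were higher adjusted over the list alone, against 0 over all genes. Cornified envelope genes were positive in 20 of 20 (camera adjusted p = 9.14e-09, adjusted p = 0.281 with an estimated correlation; 5 higher adjusted over the list alone), among them Hrnr at 371 ± 80.1 against 122 ± 22.2 CPM. Antimicrobial genes were positive in 12 of 12 (median 2.30; camera adjusted p = 4.1e-08, adjusted p = 0.198 with an estimated correlation; 6 higher adjusted over the list alone), including the iron-binding lipocalin gene Lcn2 at 32.4 ± 29.4 against 3.84 ± 1.43 CPM. The cytokine list was positive in 9 of 11 (camera adjusted p = 2.74e-06, adjusted p = 0.226 with an estimated correlation). Stress keratins and wound-activated genes were positive in 12 of 12 (camera adjusted p = 1.15e-05, adjusted p = 0.226 with an estimated correlation), led by the growth factor gene Epgn at 29.4 ± 20.1 against 3.6 ± 0.943 CPM. Cell cycle genes were positive in 19 of 19 (camera adjusted p = 4.73e-06), MCPIP1 target mRNAs in 10 of 11 (0.000173), immediate early genes in 11 of 14 (0.00162), NF-kB feedback genes in 12 of 18 (0.022) and hair shaft genes in 27 of 27 (0.0125), each with an adjusted p of 0.198 or more with an estimated correlation. The hair score was 6.76 in EMdKO mouse 3 and -1 to 0.66 in the others, and without mouse 3 the hair shaft list turned to the negative side (camera adjusted p = 0.532), while the immediate early list had an adjusted p of 0.0703. Collagen and matrix genes were negative in 17 of 21 (camera adjusted p = 0.000443; 5 lower adjusted over the list alone), skeletal muscle markers in 17 of 20 (0.00263) and monocyte and macrophage markers in 15 of 18 (0.0159). With an estimated correlation none of the 30 lists had an adjusted p under 0.198. Leaving out a library ended the calls of 6 of the 15 lists in at least 1 of 16 fits, among them skeletal muscle and NF-kB genes (0.678 and 0.0902 without MKO mouse 1) and monocytes and macrophages (0.246 without EMdKO mouse 4). The cell cycle difference fell from 0.46 to 0.26 without MKO mouse 1 and the matrix difference from -0.32 to -0.19 without MKO mouse 3. Fibronectin (Fn1) averaged 314 ± 109 CPM in EMdKO and 942 ± 732 in MKO, where its spread was large.

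The 2 single knockouts differed from each other in 117 genes, 89 higher and 28 lower in EKO than in MKO, with 2306 genes at an unadjusted p under 0.05. Of the 117, 86 did not overlap between the groups, against 10.31% of all tested genes. The neutrophil and keratinocyte alarmin genes S100a8 and S100a9 were higher in EKO by 8.07 ± 1.69 and 7.63 ± 1.47 on the log2 scale (edgeR quasi-likelihood, BH adjusted p = 0.0389 and 0.0305). EKO mouse 1 had 0.413 and 0.826 CPM of them, where the other EKO mice had 15.2 to 247 and 26.9 to 316. The MKO mice held at most 4 and 6 counts, so these folds are rough. Stfa3, a cysteine protease inhibitor, was 606 ± 418 CPM in EKO and 6.61 ± 3.73 in MKO, and the chitinase-like gene Chil1 was 81.3 ± 60.1 and 1.11 ± 0.29 (edgeR quasi-likelihood, BH adjusted p = 0.0118 for both). Il1f6 (5.83 ± 0.92), Il1f8 (2.73 ± 0.51), Rptn (4.57 ± 0.83), Flg (2.55 ± 0.52), Hrnr (2.06 ± 0.42), Lce1g (3.36 ± 0.74), Krt16 (4.73 ± 1.02) and Elovl3 (2.85 ± 0.47) were also higher in EKO past the threshold. Higher in MKO were Cxcl13, a B cell chemoattractant, at 138 ± 88.9 against 12.2 ± 1.22 CPM, Siglece (-2.30 ± 0.31), Jchain (-5.38 ± 0.94), Cd79b (-1.79 ± 0.35) and the interferon-induced membrane protein gene Ifitm6 (-2.21 ± 0.46). Col6a5 and Car4 also passed, but their MKO means of 194 ± 346 and 26.6 ± 41.7 CPM carried SDs larger than the means.

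Cell cycle genes were positive in 19 of 19 between EKO and MKO (median 1.17; camera adjusted p = 1.21e-18, adjusted p = 0.265 with an estimated correlation), with 3 higher over all genes and 19 adjusted over the list alone. The 3 were the mitotic genes Ccnb2 (1.66 ± 0.30), Cdc20 (1.57 ± 0.30) and Plk1 (1.70 ± 0.36). Cornified envelope genes were positive in 20 of 20 (camera adjusted p = 2.55e-08, adjusted p = 0.336 with an estimated correlation; 4 over all genes, 10 adjusted over the list alone). Antimicrobial genes were positive in 12 of 12 (camera adjusted p = 3.36e-06, adjusted p = 0.265 with an estimated correlation; 2 and 8). Hair shaft genes were positive in 27 of 27 (camera adjusted p = 1.13e-07), sebaceous gland genes in 12 of 15 (0.000207), the cytokine list in 9 of 11 (0.000459) and stress keratins in 9 of 12 (0.00285), each with an adjusted p of 0.265 or more with an estimated correlation. B and plasma cell genes were negative in 4 of 4 (camera adjusted p = 0.00749) and antigen presentation genes in 16 of 23 (0.0258). None of the 30 lists had an adjusted p under 0.265 with an estimated correlation. Calls of 9 of the 13 lists held in all 16 fits that left out a library, and antigen presentation and B and plasma cells had an adjusted p of 0.457 and 0.0681 without EKO mouse 1. The gene count depended on single mice: it was 510 without EKO mouse 1 and 349 without control mouse 1, but 12, 10 and 36 without EKO mouse 2, 3 and 4, 14, 22, 8 and 60 without MKO mouse 1 to 4, and 40, 73 and 63 without EMdKO mouse 1, 2 and 4. The balance turned without MKO mouse 1 (3 higher and 11 lower) and without MKO mouse 3 (2 and 6). Of the named genes called here, only Zc3h12a and Siglece kept their calls in all 16 fits, and the others lost theirs in 2 to 13. DESeq2 called 628 genes and limma-voom 1591 (826 higher and 765 lower), and the count was 48 with the hair shaft score as a covariate.

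Whether the double knockout differed from the sum of the single effects was read from the interaction of the factorial design. None of the 13633 genes passed in edgeR's quasi-likelihood test with BH adjustment, 465 had an unadjusted p under 0.05 with 682 expected by chance, DESeq2 called 3 and limma-voom 0. Insm2 had the smallest p and averaged 0.43 ± 0.123 CPM in control, 1.19 ± 0.352 in EKO, 1.14 ± 0.474 in MKO and 0.531 ± 0.125 in EMdKO. Zc3h12a had an interaction of -0.80 ± 0.32 on the log2 scale and Lyz2 one of 0.17 ± 0.42 (edgeR quasi-likelihood, BH adjusted p = 0.999 for both). Epgn was 9.08 ± 6.1 CPM in control, 11.3 ± 6.96 in EKO, 3.6 ± 0.943 in MKO and 29.4 ± 20.1 in EMdKO, and stress keratins and wound-activated genes were positive in 12 of 12 (camera adjusted p = 3.44e-05, adjusted p = 0.601 with an estimated correlation). The differences that failed the interaction test are not thereby shown to be additive.

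The mean effect of each Cre over both backgrounds was added after the data were seen. For keratinocyte loss, EKO and EMdKO together against control and MKO, 126 genes changed, 106 higher and 20 lower, and 1496 had an unadjusted p under 0.05. Il1f6 rose by 5.21 ± 0.63 on the log2 scale (edgeR quasi-likelihood, BH adjusted p = 0.00223), and Il1f8, Il1f9 and Il1a rose by 2.49 ± 0.36, 1.65 ± 0.29 and 1.87 ± 0.35. The barrier genes Lce1g (3.08 ± 0.52), Hrnr (1.69 ± 0.30), Rptn (2.72 ± 0.54) and Flg (1.68 ± 0.36) rose, as did the antimicrobial genes Defb14 (2.64 ± 0.51) and Defb6 (1.93 ± 0.40) and the sebaceous genes Elovl3 (2.04 ± 0.32), Awat1 (2.02 ± 0.40) and Fa2h (1.74 ± 0.35). Chil1, Stfa3, Slurp2, Atp12a, Alox8 and Chga rose by 3.39 to 4.43 on the log2 scale. Zc3h12a fell by 1.92 ± 0.17 (edgeR quasi-likelihood, BH adjusted p = 4.21e-05), and the laminin gene Lama1 (-1.95 ± 0.41), Rab3b (-1.50 ± 0.30) and the phospholipase gene Pla1a (-1.26 ± 0.22) fell as well. The cornified envelope list had 5 genes higher over all genes and 9 adjusted over the list alone (camera adjusted p = 4.72e-12, adjusted p = 0.253 with an estimated correlation), the cytokine list 4 and 7, the antimicrobial list 2 and 8 and the sebaceous list 3 and 7 (camera adjusted p = 7.1e-08, 8.22e-08 and 1.79e-08, each with adjusted p = 0.199 with an estimated correlation). The count was 356, 40, 46 and 47 without EKO mouse 1 to 4, 80 and 69 without EMdKO mouse 1 and 3, 49, 70, 50 and 73 without MKO mouse 1 to 4, and 223, 65, 67 and 80 without control mouse 1 to 4. Among the genes named here the call was lost in 4 of the 16 fits for Il1a, 7 for Defb14, 8 for Awat1, 9 for Rptn and Rab3b, 10 for Fa2h, 11 for Flg and Defb6, 12 for Lama1 and 13 for Alox8, and in 0 for the others. Of the 127 genes called in EKO against control without EKO mouse 1, 78 were among the 126. Both sets of calls used the other EKO mice and the same controls, so an overlap is built in and is no separate support.

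For myeloid loss, MKO and EMdKO together against control and EKO, 6 genes rose and 0 fell, where DESeq2 called 89 higher and 170 lower and limma-voom 32 and 34, and 1790 had an unadjusted p under 0.05. Marco rose by 5.36 ± 0.38, Siglece by 2.21 ± 0.22, Gbp2b by 3.25 ± 0.37 and Mrgprg by 3.83 ± 0.52 on the log2 scale (edgeR quasi-likelihood, BH adjusted p = 2.11e-06, 0.000145, 0.000586 and 0.00541). Ebi3, a subunit of the cytokines IL-27 and IL-35, rose by 1.43 ± 0.22 (edgeR quasi-likelihood, BH adjusted p = 0.016), and Cxcl13 by 2.37 ± 0.39 (edgeR quasi-likelihood, BH adjusted p = 0.0311). Marco, Gbp2b and Mrgprg lie under the level that the naming rule asks for and were named here after their values were seen. Their counts in mice without LysM-Cre were low, so their fold changes are rough. Ebi3 averaged 12.7 ± 2.71 and 12.1 ± 2.44 CPM in the groups with LysM-Cre and 4.87 ± 2.37 and 4.39 ± 1.14 in control and EKO. Lyz2 changed by -0.77 ± 0.21, which did not pass over all genes (edgeR quasi-likelihood, BH adjusted p = 0.155). Cell cycle genes were negative in 19 of 19 (camera adjusted p = 3.77e-16, adjusted p = 0.297 with an estimated correlation; 0 lower over all genes, 17 adjusted over the list alone) and antigen presentation genes positive in 19 of 23 (camera adjusted p = 8.54e-07, adjusted p = 0.626 with an estimated correlation; 3 adjusted over the list alone). The hair shaft list moved with this effect too, negative in 27 of 27 (camera adjusted p = 3.36e-15, adjusted p = 0.626 with an estimated correlation). The count was 25 without EKO mouse 1, 14 without control mouse 3 and 12 without EMdKO mouse 4, and the Cxcl13 call was lost in 8 of the 16 fits that left out a library and the Ebi3 call in 3. With the mouse numbers of the file names as a block the Cxcl13, Ebi3 and Mrgprg calls were lost, and with limma-voom the Mrgprg call (adjusted p up to 0.0666 for Mrgprg). Of the 12 lists called for this effect, 6 kept their calls in all 16 fits.

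Effects against the shared controls were compared across genes, which are not independent replicates. The log2 fold changes of MKO and EMdKO correlated with r = 0.69, those of EKO and EMdKO with r = 0.63 and those of EKO and MKO with r = 0.28, where unchanged groups against shared controls gave r = 0.50 in simulation. The covariance was 0.198 for MKO and EMdKO, 0.121 for EKO and EMdKO and 0.064 for EKO and MKO, against simulated values of 0.07, 0.069 and 0.07. With the controls split 2 and 2 the mean r was 0.29, 0.10 and -0.07 in that order. Single splits ran from -0.03 to 0.44, from -0.28 to 0.38 and from -0.52 to 0.26. Genes were simulated independently, so the simulated values hold no tissue difference, such as in hair, that moves many genes together. An r or covariance above the simulated one may therefore come from the 4 shared controls and was not read as a shared effect. MKO and EMdKO shared 3 higher calls, Marco, Siglece and Gbp2b, both against the same 4 controls.

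The circadian clock list was positive in 11 of 13 in MKO against control (camera adjusted p = 0.0148, adjusted p = 0.372 with an estimated correlation) and negative in 12 of 13 in EKO against MKO (0.00433 and 0.265). It was positive in 12 of 13 in EMdKO against EKO (0.0439 and 0.487) and in 11 of 13 in the mean myeloid effect (0.00944 and 0.297), led there by Hlf, a clock-controlled transcription factor gene, at 29.8 ± 13 CPM in MKO against 15 ± 6.33 in control. Its camera adjusted p was 0.371 in EKO against control, 0.412 in EMdKO against control, 0.131 in EMdKO against MKO, 0.662 for the interaction and 0.121 for keratinocyte loss. With an estimated correlation its lowest adjusted p was 0.265. A lean of the whole list to 1 side was not read as a difference in the time of day of collection, which was not tested. The call in MKO was lost without control mouse 3 (0.0627), and that in EMdKO against EKO in 4 of 16 fits (0.33 without EMdKO mouse 1, where the score difference fell from 0.24 to 0.08). The sex-linked list passed in no contrast, with camera adjusted p of 0.482, 0.744 and 0.412 for EKO, MKO and EMdKO against control, 0.0704, 0.657 and 0.358 for EMdKO against EKO, EMdKO against MKO and EKO against MKO, and 0.303, 0.802 and 0.193 for the interaction and the mean effects.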

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

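In each group of 4 mice, a value was singled out when the gap between the most extreme mouse and its nearest neighbor took up most of the group's range (Dixon's rule at its 95% level). Chance singles out about 1 in 20 groups. Of 540 groups tested, 39 were singled out where 27 are expected, 15 of them in EKO mouse 1. They were 12 list scores and 27 gene levels, and no measure of library quality was among them. The tests for a mislabelled sample, less epidermis, macrophage number and the Cre insertion in Lyz2 were chosen after the results were seen. Those for hair follicle stage and for DNA linked to the Cre insertion were written before.

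EKO mouse 1 lay apart from the other EKO mice in 3 list scores and 12 genes. Its cornified envelope score was 7.39 (others 9.02 to 9.13), its cytokine score 3.06 (4.98 to 5.26) and its hair follicle stem cell score 6.66 (6.16 to 6.22). In CPM it had 0.516 of Il1f6 (79.3 to 92.4), 58.5 of Il1f9 (252 to 325), 3.51 of Il1a (29.4 to 40.6), 0.723 of Defb14 (14.2 to 22.3), 8.67 of Lce1g (129 to 147), 92.8 of Hrnr (602 to 684), 458 of Krt1, 50.1 of Elovl3 (from 145 upward), 1.45 of Lcn2 (19.4 to 31.5), 12.4 of Stfa3 (698 to 992), 12.7 of Slurp2 (195 to 328) and 2.06 of Atp12a (111 to 218).

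Other mice stood apart from their groups more rarely. Among list scores these were MCPIP1 target mRNAs in control mouse 2 (4.12; others 2.75 to 2.94), cell cycle in control mouse 1 (4.56; 3.33 to 3.47), skeletal muscle in control mouse 1 (9.71; 10.49 to 10.53), immediate early genes in EMdKO mouse 3 (7.05; 6.16 to 6.23), mast cells in EMdKO mouse 3 (3.85) and MKO mouse 1 (4.05), hair shaft in MKO mouse 4 (3.01), sebaceous gland in MKO mouse 1 (5.48) and endothelial cells in MKO mouse 1 (5.13). Among genes, in CPM, they were Defb14 in control mouse 2 (4.46), Defb6 in control mouse 1 (4.46), Styk1 in control mouse 1 (4.46), Il1f8 in control mouse 4 (5.5), Dbn1 in control mouse 4 (27.4) and Islr in control mouse 3 (51.3). In EMdKO they were Zc3h12a in mouse 4 (4.41) and Krt35 (10.8), Mcm6 (30.1), Irf7 (25.4) and Tmem100 (11.5) in mouse 3. In MKO they were Serpinb3a in mouse 2 (0.126), Mcm6 in mouse 1 (25.1) and Slurp2 in mouse 1 (1.57), and in EKO Hspa1a in mouse 2 (21.5).

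In 8 gene lists the effect of 1 knockout differed with the other by the camera test of the interaction, where no single gene passed. The adjusted p was 3.44e-05 for stress keratins, 6.25e-05 for immediate early genes, 0.000125 for hair shaft, 0.00448 for sebaceous gland (13 of 15 positive) and for skeletal muscle (20 of 20 negative), 0.00728 for MCPIP1 targets, 0.0277 for adipocytes and 0.0328 for melanocytes. With an estimated correlation none was under 0.601, and only the stress keratin and immediate early lists kept their calls in all 16 fits that left out a library. The others reached 0.13 and 0.178 without EKO mouse 1 (MCPIP1 targets, sebaceous gland), 0.185 without EMdKO mouse 3 (hair shaft), 0.685 without MKO mouse 1 (skeletal muscle), 0.444 without control mouse 4 (adipocytes) and 0.34 without control mouse 1 (melanocytes).

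EKO mouse 1 lacked changes that the other EKO mice shared. A mislabelled sample could not be excluded: its Zc3h12a level of 11.7 CPM (113 counts, counting interval 9.61 to 14) lay just under the lower bound of 12.4 CPM predicted for a mouse with intact keratinocytes, which the first form of the test would have read as against mislabelling; the counting interval was added to the rule after this value was seen. Less epidermis in the piece went against the values as the whole cause. The basal keratinocyte list was lower by a median of -0.44 and the genes higher in the other EKO mice by -2.36. Of those 113 genes, 111 passed the filter with all libraries. They were chosen in a fit without EKO mouse 1, so part of their fall follows from that choice. Less epidermis as a part of the cause stays open. Krt14 was 676 CPM against 2400, 4130 and 2330 CPM in EKO mice 2, 3 and 4. The muscle and adipocyte scores of 11.17 and 7.38 were the highest in EKO. Hair follicle stage also went against the values, predicting a shift of 0.03 (interval -0.16 to 0.22) where -2.53 was seen in the same chosen genes. That slope came from the libraries in which the genes were chosen, and the choice favors genes that vary little within groups. A slope near 0 is thus partly built in, and the test does not exclude hair follicle stage.

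Marco, Siglece and Gbp2b were higher in both groups with LysM-Cre. More macrophages in the tissue went against the values, as the 18 tested monocyte and macrophage markers had a median change of -0.08 (mean 0.04, standard error 0.14). DNA linked to the Cre insertion in Lyz2 also went against them, as 0 of the 6 called genes lay on chromosome 10. A genetic background elsewhere in the genome and an effect of Cre itself remain possible, because no mice with Cre and an intact Zc3h12a were among the samples. A change in the state of the macrophages was not tested.

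Lyz2 was lower with LysM-Cre, at 224 ± 41.7 CPM in 8 carriers and 382 ± 127 CPM in 8 other mice (exact permutation p = 0.0101 over 12870 assignments). EKO mouse 1, which carries no LysM-Cre, went the other way with 147 CPM, the lowest of all mice. The carriers had 176 to 295 CPM and the remaining mice without LysM-Cre 323 to 548. Fewer macrophages went against the values, as the 17 other markers had a median change of -0.07, with 10 lower and 7 higher. Cre inserted in 1 of the 2 Lyz2 copies fits. The change of -0.77 had an interval from -1.23 to -0.31, built on the approximate standard error, which held a halving. The number of Cre copies is not given in the labels, so the reading could be checked only against this 1 value.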

How the results depend on the processing

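Marco and Zc3h12a kept their calls in every fit that left out a library, and Zc3h12a in EKO against control gained 1 without EKO mouse 1 or MKO mouse 1. Marco in MKO lost its call with limma-voom (adjusted p = 0.0664). Where a value below moved, the cause was not tested. Genes changed numbered, with DESeq2 and limma-voom, 59 and 4 in EKO, 116 and 0 in MKO and 73 and 8 in EMdKO against control, 147 and 8 in EMdKO against MKO, 628 and 1591 in EKO against MKO, 316 and 588 for keratinocyte loss and 259 and 66 for myeloid loss. DESeq2 gave 9 in EMdKO against EKO and 3 for the interaction. Without a filter on low counts EKO against control had 3 and EMdKO against MKO 9, and with a muscle covariate these had 7 and 10 and myeloid loss 13. The hair covariate gave 1 in MKO against control, 2 in EMdKO against MKO and 48 in EKO against MKO. Fits on the 2 groups alone gave 1 in MKO, 10 in EMdKO against control and 90 in EMdKO against MKO. Leaving out 1 library gave 0 to 127 (EKO), 1 to 5 (MKO) and 2 to 40 (EMdKO) against control, 1 to 3 in EMdKO against EKO, 1 to 95 in EMdKO against MKO, 8 to 510 in EKO against MKO, 0 to 0 for the interaction, 40 to 356 for keratinocyte loss and 4 to 25 for myeloid loss. Zc3h12a in EKO was called at -1.51 with DESeq2 and with the muscle covariate, -1.78 with limma-voom and -1.50 without a filter, and ranged from -1.70 to -1.40 over the left-out libraries.

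The mouse number as a replicate block lowered the calls of EKO against MKO to 46 and moved no other count by more than 1.5 times. EMdKO against control kept a count of 4, but as 2 higher and 2 lower, with the Gbp2b call lost. The mouse numbers of that block are from the titles, but file names number the EMdKO and MKO mice 2 to 5. A replicate block by the file names, added after the data were seen, gave 2 in MKO against control, 1 in EMdKO against EKO, 2 in EMdKO against MKO and 3 for myeloid loss, and 92 in EKO against MKO. Only 5 of 16 libraries correlated best with their own number in the titles and 3 with that in the file names, so neither was read as a pairing. Of 79 list calls in the 7 contrasts, 0 held with an estimated correlation, 6 with fry and 8 with its mixed form. With the hair covariate, list tests changed sign and had adjusted p of 0.971 (basal keratinocytes, EMdKO against control), 0.991, 0.835 and 0.920 (hair shaft, EMdKO against EKO, EMdKO against MKO and EKO against MKO) and 0.747 (melanocytes, myeloid loss). For the hair shaft list this was fixed by construction, since its own score was the covariate. Hair shaft in EMdKO against MKO ran from 7.03e-05 to 0.532 over the left-out libraries. Small values that did not pass changed sign. Lyz2 for keratinocyte loss was 0.03 with library totals and 0.02 without a filter, and ran from -0.12 to 0.13 over the left-out libraries. Over the left-out libraries Lyz2 ran from -0.33 to 0.17 in EKO, -0.06 to 0.18 in EMdKO against MKO and -0.09 to 0.41 in the interaction, Zc3h12a from -0.06 to 0.27 in MKO and Krt14 from -0.64 to 0.07 in the interaction. With the controls split 2 and 2, the mean r between EKO and MKO was -0.07 and between MKO and EMdKO 0.29. For 219 pairs of a named gene and a contrast, 2114 values stayed on their side over the alternatives other than left-out libraries, 115 became stronger, 109 weaker and 2 changed sign. With 1 library left out, 3040 stayed, 63 became stronger, 387 weaker and 14 changed sign. The term for sex was not run because all mice carried Y-linked transcripts. At this depth a level under 3 counts cannot be told from 0.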

Other observations

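Nerve and vessel genes differed between the groups when tested over genes. Schwann cell and nerve genes were positive in 10 of 10 in MKO against control (median 0.38; camera adjusted p = 0.00333, adjusted p = 0.372 with an estimated correlation), led by the cadherin gene Cdh19 at 15.8 ± 2.38 against 10.3 ± 5.02 CPM, but the call was lost without control mouse 4 (0.151, the score difference falling from 0.39 to 0.24). They were negative in 10 of 10 in EKO against MKO (0.000494 and 0.268) and in 9 of 10 in EMdKO against MKO (0.000125 and 0.226). Endothelial and lymphatic genes were positive in 12 of 14 in MKO (0.0101 and 0.558), with the tight junction gene Cldn5 at 10.9 ± 1.9 against 7.4 ± 2.64 CPM. That difference lay mainly in MKO mouse 1 (score 5.13, others 4.55 to 4.59) and control mouse 1 (4.11, others 4.53 to 4.70), with an exact permutation p of 0.486 over mice and a camera adjusted p of 0.374 without MKO mouse 1, and MKO mouse 1 also had the highest muscle and adipocyte scores of all mice, 11.84 and 8.03. Endothelial genes were negative in 13 of 14 in EKO against MKO (0.00179) and in 12 of 14 in EMdKO against MKO (0.022), where the estimated correlation gave 0.402 and 0.508. Both calls were lost without MKO mouse 1 (0.0589 and 0.572). For keratinocyte loss, collagen and matrix genes were negative in 19 of 21 (0.000127), Schwann cell genes in 10 of 10 (0.00115) and endothelial genes in 14 of 14 (0.0347), while cell cycle genes were positive in 19 of 19 (5.01e-11), MCPIP1 targets in 8 of 11 (0.0123), stress keratins in 8 of 12 (0.0305) and NF-kB genes in 13 of 18 (0.0487). The estimated correlation gave these an adjusted p of 0.278 or more, and the MCPIP1, stress keratin, endothelial and NF-kB lists lost their calls in 2, 7, 8 and 11 of the 16 fits that left out a library.

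Type I interferon genes were negative in 19 of 20 for myeloid loss (median -0.55; camera adjusted p = 0.00944, adjusted p = 0.803 with an estimated correlation), with the interferon regulator gene Irf7 at 15 ± 6.98 CPM in EMdKO and 33.6 ± 15.5 in EKO. Among controls, mouse 2 stood above the rest, with a score of 5.68 where the other controls had 3.06 to 3.68 and MKO had 3.21 to 4.12, and with 115 CPM of Irf7 where the other controls had 10.9 to 27.1, and without it the list had an adjusted p of 0.378 for myeloid loss. The interferon genes were also negative in 19 of 20 in EMdKO against EKO (0.00948 and, with an estimated correlation, 0.852) and positive in 16 of 20 in EKO against MKO (0.0351 and 0.751), while antigen presentation genes went the other way. Both interferon calls were lost without EKO mouse 2 (0.288 and 0.361, the score differences falling from -0.47 to -0.24 and from 0.48 to 0.25). For myeloid loss, B and plasma cell genes were positive in 4 of 4 (camera adjusted p = 0.000155, adjusted p = 0.167 with an estimated correlation), endothelial genes in 13 of 14 (0.00944) and Schwann cell genes in 9 of 10 (0.0303), the last 2 with 0.628 or more. Negative were melanocyte markers (6 of 8, 0.00944), stress keratins (9 of 12, 0.0221), cornified envelope genes (16 of 20, 0.0396) and antimicrobial genes (11 of 12, 0.0396). The estimated correlation gave these 4 lists an adjusted p of 0.628 or more. Of the 16 fits that left out a library, 8 ended the antimicrobial call, 8 the cornified envelope call, 6 the stress keratin call, 4 the Schwann cell call and 1 the endothelial call. The lists that passed in none of the 9 contrasts were chemokines (lowest camera adjusted p = 0.203), type 2 inflammation and itch (0.37), neutrophils (0.439), dendritic and Langerhans cells (0.271), mast cells (0.262) and hair follicle stem cells (0.529).

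Hair shaft genes were prominent in the largest component of difference between mice. Whether follicle stage caused that component was not tested. The first principal component held 40.7% of the variance and the second 16.2%, and 23 of 27 hair shaft genes were among the 100 largest loadings of the first. Hair scores ran from -1.14 to 9.56. They overlapped between the groups but were lower on average with LysM-Cre. Their means ± SD were 0.02 ± 1.99 in MKO and 1.41 ± 3.64 in EMdKO, against 5.05 ± 4.44 in control and 4.05 ± 2.36 in EKO. Pigment differences between groups may follow the follicle stage of single mice. The melanocyte test for myeloid loss had a camera adjusted p of 0.747 with the hair covariate. That covariate was itself lower with LysM-Cre, so this test cannot tell follicle stage from genotype.

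Other ways of dividing the same mice were tried after the results were seen. For EKO against control and the interaction the real count was 0, so all 35 splits and all 100 relabellings were as large by construction and decide nothing. The highest other counts were 358, dividing EKO mouse 1 and control mice 1 to 3 from the rest, and 2. Chance cannot be excluded for EMdKO against control (real 4, highest other 209, 2 of 35 as large) or for EKO against MKO (real 117, highest other 280, 2 of 35). Other splits called fewer than the real one in MKO against control (real 4, highest other 1, 1 of 35 as large, the real split itself), EMdKO against EKO (real 2, highest other 0, 1 of 35) and EMdKO against MKO (real 1, highest other 0, 1 of 35). The 100 relabellings of the mean effects included the real one. For keratinocyte loss 1 of 100 was as large, the real one itself (real 126, highest other 0), and for myeloid loss 3 of 100 (real 6, highest other 319). Both effects were read from the same relabellings, and the 319 for myeloid loss shows that a random division can call more than 126 genes. The highest other count of 0 therefore does not place 126 out of reach of chance.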
